A study of Mus musculus with 6 samples.

How the data were processed

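RNA levels were measured on 6 single-colour microarrays, 3 of myeloid cells from the infarcted left ventricle (heart 1, heart 2 and heart 4) and 3 of myeloid cells from the spleen (spleen 1, spleen 2 and spleen 4). All came from C57BL/6N wild-type mice 3 days after acute myocardial infarction. Per the labels' protocols, the cells were sorted by flow cytometry for high CD45 and CD11b and for low staining with antibodies to lineage antigens of B cells, T cells, natural killer cells and neutrophils (Ly6G). RNA was purified with a kit for small samples, amplified in a single round to amino allyl cRNA and coupled to a fluorescent dye, per the labels' protocols. The labels state that spleens and ventricles were analysed individually. They do not state whether a spleen and a ventricle with the same number came from the same animal, and a sample with the number 3 was not analysed here.

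The deposited scanner files hold an intensity per spot on a linear scale, which the authors obtained with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. Per the file headers, the processed signal is already corrected for background by that program and is not scaled between arrays. Each file has 44397 spots, 43020 of them not controls, for 39429 probes. The deposited value table holds log2 values. In the comparison with the scanner files, its differences between arrays matched those of quantile-normalized log2 processed signals (r between 0.9998 and 1, slope between 1.002 and 1.008, across 19310 probes for 15 pairs of arrays). The median of every column was 0. Its scale and direction were settled by this comparison, while the baseline that was subtracted from each probe stays unknown, so it served only as an alternative for differences between the tissues.

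The processed signal was taken as log2 minus the 75th percentile of log2 signals on the same array, after control spots and spots marked by the scanner program as outliers were left out. Spots of the same probe were averaged (399 probes had 10 spots each). A probe was tested where the program called it well above background on all 3 arrays of at least 1 tissue. That filter left out 17624 probes, a further 4 had too few usable spots, and 21801 remained. Of the 39429 probes, 26412 were named by matching their accession, without version, to a RefSeq gene table of the GRCm38 assembly, which was used for names only. The others kept the name in the file, which can be old, and 35777 probes had a name. A gene was represented by its tested probe with the highest mean level, which gave 16365 genes, 3327 of them with more than 1 tested probe. Coordinates are those of the probes in the scanner files, in the mouse build mm9, and positions relative to exons were not analysed here. Paralogs with near-identical sequence can share signal on probes, as for the haemoglobin alpha genes, the Mrgpra2 genes, the Stfa genes, and Ccl2, Ccl7 and Ccl12, and their values are uncertain to that extent.

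Heart was compared with spleen with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with data.table (version 1.17.8) for file handling, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Fold changes are log2, heart minus spleen, with the standard error (SE) of the moderated fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Where a gene was not well above background on any array of a tissue, only a bound is given. It sets the mean of the brighter tissue against the mean of, for each dim array, the higher of the lowest level among probes well above background and the probe's own level. For genes well above background on only some arrays of a tissue, the change with each dim array held at that floor, or at the probe's own level if higher, is given beside the fitted one. No spot was saturated on any array.

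The genes named are the 10 with the largest rise and the 10 with the largest fall among called genes measured on all arrays with no overlap between tissues, and the 5 with the largest bound in each direction. From each gene list they are the 3 called members with the largest change and the brightest member that was not called. Of the genes so picked, 2 are not reported here; counts over the picked genes include them. Metrnl, Mydgf and the sort markers are named whatever their values. The 30 lists hold 570 genes, of which 566 had a probe (Ly6g, Ly6c2, Ighm and Hspa1b had none) and 479 were tested. Lists were tested with camera at a preset correlation of 0.01 between genes and adjusted over the 30 lists. Camera with a correlation estimated for each list and fry were run beside it. Camera compares a list with all other genes, whereas fry tests whether the list's genes move, on balance, in a single direction. Missing values were filled with the tissue mean for the list tests only. The groups, this test, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

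The alternatives were quantile or median scaling, normexp background correction (offset 50), the deposited value table, no filter on dim probes, probes well above background on all 6 arrays, and the mean of a gene's probes. Others were the replicate number, the date in the titles or the slide as a block, the samples of the earlier date alone, each sample left out, a variance prior with trend and robust fitting, array weights, and stricter thresholds. Slide as a random block, array weights estimated per tissue, and a per-gene test with a separate variance for each tissue and no moderation were chosen after seeing the data. Slide 1 held spleen 1 and spleen 2, slide 2 held spleen 4 and heart 1, and slide 3 held heart 2 and heart 4, and scans followed the slides. Samples numbered 1 and 2 share a date in their titles and samples numbered 4 have another.

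The fit was tested on simulated data for this comparison over 16365 genes, with 200 genes changed in each of 5 sets. With the same spread in both tissues, 14.9% of genes changed by a log2 of 1 were recovered, 61.8% of those changed by 2 and 87.6% of those changed by 4, and 6% of calls were false. The shifted list was called in 5 of 5 sets, and 0 of 145 unshifted lists were called by camera. The simulated genes varied independently, whereas the estimated correlation of the shifted list, cell cycle, was 0.889 in the data. False calls of lists with correlated genes were thus not tested. With each tissue's own measured spread, 612 of 1000 changed genes were recovered, and 138 of 750 calls (18.4%) were false. These shares of false calls depend on how many genes were changed and need not hold for the data. The number of arrays, 3 per tissue, limits the precision of all values.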

Results

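Myeloid cells are innate immune cells that include monocytes, macrophages, dendritic cells and granulocytes, and the spleen holds a reserve of monocytes that can enter injured tissue. The comparison asked how the RNA levels of such cells in the infarcted left ventricle differed from those in the spleen 3 days after acute myocardial infarction, with 3 samples per tissue. On each array, between 52.8% and 63.6% of probes were well above background. The mean was 54.6% ± 1.85 (SD, n = 3) for heart and 59.8% ± 3.95 (SD, n = 3) for spleen. The 75th percentile of the processed signal lay between 1533 and 1982 intensity units, and 0 spots were saturated. After filtering, 16365 genes were compared.

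The 3 heart samples resembled each other more closely than the 3 spleen samples did. Across probes, which are not independent replicates, the mean correlation was 0.991 between heart samples, 0.949 between spleen samples and 0.906 between heart and spleen samples. The principal component with the largest share of the variance (67.8%) parted the tissues, and spleen 4 lay nearest to the hearts on it (−51.24, against −118.5 for spleen 1, −95.75 for spleen 2 and 82.8 to 94.93 for the hearts). The median SD per gene was 0.143 log2 units over the heart samples and 0.41 over the spleen samples, and it was larger in spleen for 84.3% of genes.

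As lists, chemokines, inflammatory cytokines, secreted repair factors and matrix genes had higher RNA levels in the heart samples than in the spleen samples, and neutrophil markers and cell cycle genes had lower levels, in a test that presets the correlation between genes. With that correlation estimated, none of the 30 lists passed (lowest adjusted p 0.064). Arg1, the arginine-degrading enzyme of alternatively activated macrophages (mm9 chromosome 10, 24636194 to 24636253), had the largest rise among genes measured on all arrays. Its log2 level was 5.42 ± 0.40 (SD, n = 3) in heart and −3.54 ± 1.51 (SD, n = 3) in spleen, a log2 fold change of 8.96 ± 0.73 (SE, adjusted p = 0.00172). The largest fall among genes measured on all arrays was that of Ltf, which encodes the neutrophil granule protein lactoferrin (mm9 chromosome 9, 110942873 to 110942932). Its log2 level went from 6.22 ± 1.09 (SD, n = 3) in spleen to −2.83 ± 0.82 (SD, n = 3) in heart, a log2 fold change of −9.04 ± 0.64 (SE, adjusted p = 0.00101). Ccl7, a chemokine that attracts monocytes (mm9 chromosome 11, 81860656 to 81860715), was at least 3588-fold higher in heart (adjusted p = 9.62e-06) and was not well above background on any spleen array.

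Of the 16365 genes, 2521 were called by limma, 1454 higher in heart and 1067 lower, and 5172 had an unadjusted p under 0.05. A change of at least 2-fold was found for 2066 of the called genes (1182 higher, 884 lower). In all 2521 called genes the 3 values of a tissue did not overlap those of the other, which held for 6653 tested genes (40.7%) and for 10% by chance. Of the genes called higher, 69 were not well above background on any spleen array, and of those called lower, 196 were not well above background on any heart array. The median log2 fold change of all genes was 0.10, and 0.22 with arrays scaled to their median, so a change of that size is within the choice of scaling. Of 506 called genes with more than 1 tested probe, 5 had another probe called in the opposite direction.

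The count depended on single samples and on the treatment of slide and variance. It was 444 without heart 1, 477 without heart 2 and 503 without heart 4, when the pooled variance rests more on the spleen samples, and 4090 without spleen 4. A per-gene test with a separate variance for each tissue and no moderation, chosen after seeing the data, called 48 genes. In simulated data with each tissue's own spread, 18.4% of calls of the pooled-variance test were false, and 7.32% of unchanged genes had an unadjusted p under 0.05. Only 200 of 16365 genes were changed in each simulated set. The share of false calls depends on how many genes truly differ, so 18.4% is not an estimate for the 2521 calls. With slide as a fixed block, where only slide 2 holds both tissues, 85 genes were called (72 higher, 13 lower), and with slide as a random block, chosen after seeing the data, 2339. With the date in the titles as a block 2319 genes were called, and 1765 within the earlier date. Of 1781 genes called on the 4 arrays other than heart 1 and spleen 4, with 2 values per tissue and a value in that pair required, 1685 (94.6%) had the same direction in that slide 2 pair, against 66.7% of all genes. Of 1755 genes called on the arrays of the earlier date under the same requirement, 1641 (93.5%) had the same direction in heart 4 minus spleen 4, the only pair of the later date, against 66.6% of all genes.

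**Figure D1:**
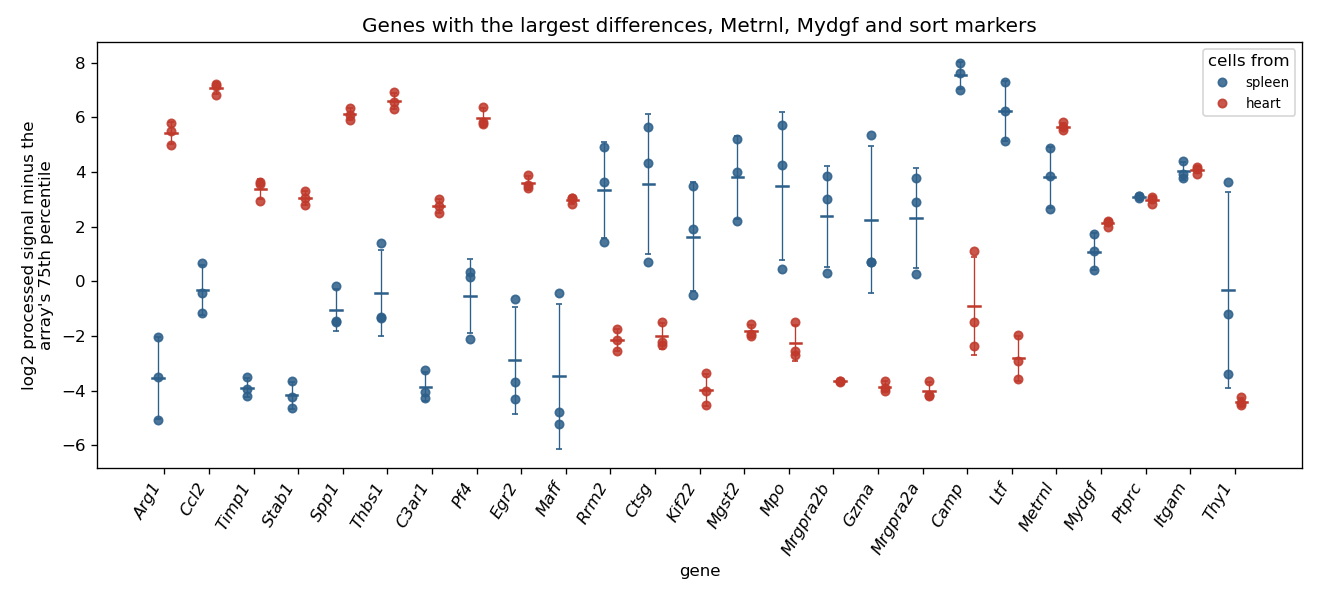
Log2 level, relative to the 75th percentile of its array, of the 20 genes with the largest changes measured on all arrays and of Metrnl, Mydgf, Ptprc, Itgam and Thy1, with a point per sample and the mean ± SD of each tissue (n = 3). The heart samples of Arg1 had a mean of 5.42 against −3.54 in spleen, those of Ltf −2.83 against 6.22, while Ptprc differed by −0.12.

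Chemokines, the secreted proteins that recruit leukocytes, formed the list with the largest rise. Of 20 tested, 16 were called higher (18 adjusted over the list alone), with a median log2 fold change of 5.41, or 5.16 with genes below background at their bound (camera adjusted p = 1.83e-15, adjusted p = 0.064 with an estimated correlation). Beside Ccl7, the neutrophil-attracting chemokines Cxcl3 and Cxcl1 were at least 815-fold (adjusted p = 1.05e-05) and at least 520-fold higher (adjusted p = 8.21e-05). Ccl8 was at least 57.2-fold higher (adjusted p = 0.000336). Ccl2, a ligand of the monocyte receptor Ccr2, rose by a log2 of 7.39 ± 0.46 (adjusted p = 0.000764) and Pf4 by 6.53 ± 0.65 (adjusted p = 0.00329). Ccl6 did not pass the test (1.30, adjusted p = 0.0732; 0.00554 without spleen 4).

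Of 20 inflammatory cytokines and enzymes, 14 were called higher (15 adjusted over the list alone). The median was 2.30 (camera adjusted p = 3.12e-07, adjusted p = 0.064 with an estimated correlation). Il1a was at least 24.9-fold higher (adjusted p = 0.000663). Il6 rose by 7.17 ± 0.91 (adjusted p = 0.00668) and Ptgs2, the inducible cyclooxygenase, by 8.81 ± 1.57 (adjusted p = 0.0178), both well above background on 1 of 3 spleen arrays (6.74 and 7.36 with the dim arrays at the lowest level well above background, the floor). Ptges, a prostaglandin E synthase, was at −0.39 (adjusted p = 0.146; −0.75 and 0.0421 with quantile scaling). Immediate early and heat shock genes, which respond within minutes to stimulation and to cell stress, moved with these lists, with 11 of 20 called higher and 1 lower (16 and 1 adjusted over the list alone). The median was 2.21 (camera adjusted p = 3.12e-07, adjusted p = 0.18 with an estimated correlation). Among them were Fosb (5.68 ± 0.98, adjusted p = 0.0163), Ier3 (5.38 ± 0.29, adjusted p = 0.000507) and the phosphatase gene Dusp1 (3.56 ± 0.40, adjusted p = 0.00465). Hsp90aa1 did not pass (0.83, adjusted p = 0.128). With heart 1, heart 2 or heart 4 left out, the numbers called higher were 12, 12 and 13 for chemokines, 8 each time for inflammatory genes and 5 each time for immediate early genes. The calls of Ptgs2 (adjusted p 0.0755 to 0.0774) and Fosb (0.0688 to 0.0749) ended in each of these 3 fits.

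Secreted growth and repair factors rose as a list, with 10 of 26 called higher (16 adjusted over the list alone). The median was 1.37 (camera adjusted p = 1.33e-06, adjusted p = 0.064 with an estimated correlation). The matrix protein and cytokine gene Spp1 (osteopontin) rose by 7.15 ± 0.39 (adjusted p = 0.000517) and Thbs1 (thrombospondin 1) by 7.01 ± 0.74 (adjusted p = 0.00377). Areg, a ligand of the epidermal growth factor receptor, was at least 33.9-fold higher (adjusted p = 0.00101). Metrnl, which encodes the secreted protein meteorin-like (mm9 chromosome 11, 121577358 to 121577417), was at 5.66 ± 0.14 (SD, n = 3) in heart and 3.80 ± 1.11 (SD, n = 3) in spleen. Its values were higher in all 3 heart samples, but its log2 fold change of 1.86 ± 0.53 did not pass the test (adjusted p = 0.0619, from 0.00962 to 0.609 over the alternatives; 0.00962 without spleen 4, 0.0482 with the date block). Mydgf, myeloid-derived growth factor (mm9 chromosome 17, 56315994 to 56316053), was at 2.12 ± 0.11 (SD, n = 3) and 1.08 ± 0.67 (SD, n = 3), a fold change of 1.04 ± 0.34 (adjusted p = 0.0917; 0.0149 without spleen 4). Grn, the precursor of granulins, was at 1.14 (adjusted p = 0.153). The numbers of repair factors called higher without heart 1, heart 2 or heart 4 were 7, 8 and 7.

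Matrix proteases and extracellular matrix genes had 14 of 21 members called higher (17 higher and 1 lower adjusted over the list alone). The median was 3.14, or 2.92 with bounds (camera adjusted p = 4.13e-10, adjusted p = 0.064 with an estimated correlation). The metalloprotease inhibitor gene Timp1 was among those called (7.28 ± 0.28, adjusted p = 0.000175). Tgfbi did not pass (1.28, adjusted p = 0.0647; 0.045 without spleen 1 and 0.0174 without spleen 4). Fibroblast markers were higher in the same samples, with 6 of 10 called higher (6 higher and 1 lower adjusted over the list alone). The median was 4.09, or 3.65 with bounds (camera adjusted p = 0.000452, adjusted p = 0.106 with an estimated correlation). Col3a1 was at least 25.5-fold higher (adjusted p = 0.00749), Mgp at least 10.5-fold (adjusted p = 0.00101), and the glycoprotein gene Pdpn rose by 8.68 ± 0.63 (adjusted p = 0.00116, above background on 1 of 3 spleen arrays; 7.74 with dim arrays at the floor). Gsn did not pass (0.27, adjusted p = 0.626, and −0.09 with quantile scaling). Of the fibroblast and cardiomyocyte lists, 10 of 15 and 11 of 20 members were tested. A marker dim in spleen was tested only if well above background on all 3 heart arrays, which tilts these counts towards higher in heart. Cardiomyocyte markers had 4 of 11 called higher (5 adjusted over the list alone). The median was 1.19 (camera adjusted p = 0.016, adjusted p = 0.18 with an estimated correlation). Actc1 and Mb were at least 4.76-fold (adjusted p = 0.00652) and at least 4.31-fold higher (adjusted p = 0.0148), and Myl2 rose by 2.30 ± 0.49 (adjusted p = 0.0281, above background on 2 of 3 spleen arrays; 2.27 with the floor). The atrial peptide gene Nppa did not pass (0.24, adjusted p = 0.695). The call of the cardiomyocyte list ended without spleen 1 (adjusted p = 0.052), without a filter on dim probes (0.157) and with array weights per tissue (0.0545), and it and the fibroblast list ended among probes above background on all 6 arrays (0.677 and 0.169). Without heart 1, heart 2 or heart 4, 9, 9 and 10 matrix genes, 4, 4 and 5 fibroblast markers and 1, 1 and 2 cardiomyocyte markers were called higher. The calls of Mb (adjusted p 0.0548 to 0.0707) and Myl2 (0.0734 to 0.109) ended, that of Myl2 also without spleen 2 (0.0527).

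Genes of alternative activation, the programme induced by interleukin 4 and related signals, had 10 of 17 members called higher (11 adjusted over the list alone). The median was 2.00 (camera adjusted p = 6.81e-06, adjusted p = 0.18 with an estimated correlation). They were led by Arg1, the scavenger receptor gene Stab1 (7.23 ± 0.29, adjusted p = 0.000191) and the transcription factor gene Egr2 (6.49 ± 0.90, adjusted p = 0.00911; 0.0532 without heart 4). Chil3, near the top of the signal range where differences can be compressed, did not pass (−0.33, adjusted p = 0.418). Genes of lysosome, phagocytosis and lipid handling had 16 of 34 called higher (21 adjusted over the list alone). The median was 1.67 (camera adjusted p = 2.93e-10, adjusted p = 0.232 with an estimated correlation). Gpnmb rose by 5.53 ± 0.96 (adjusted p = 0.0166) and Gas6, which bridges dying cells to their receptors, by 5.09 ± 0.53 (adjusted p = 0.00355), each well above background on 2 of 3 spleen arrays (5.21 and 4.98 with the floor). Its receptor gene Mertk rose by 3.70 ± 0.77 (adjusted p = 0.0259). Lgals3 did not pass (0.76, adjusted p = 0.14). When heart 1, heart 2 or heart 4 was left out, 7, 7 and 6 alternative activation genes and 6, 5 and 5 lysosome genes were called higher. The calls of Gpnmb (adjusted p 0.0696 to 0.0744) and Mertk (0.088 to 0.101) ended, that of Mertk also without spleen 2 (0.0504). Without spleen 2, 10 lysosome genes were called higher, and 23 without spleen 4.

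Glycolysis and hypoxia-inducible genes had 12 of 27 members called higher (17 adjusted over the list alone). The median was 0.89 (camera adjusted p = 3.79e-06, adjusted p = 0.232 with an estimated correlation). The glucose transporter gene Slc2a1 rose by 2.47 ± 0.22 (adjusted p = 0.00212), the oxygen sensor gene Egln3 by 2.56 ± 0.55 (adjusted p = 0.0282), and P4ha2, a collagen prolyl hydroxylase gene, was at least 6.12-fold higher (adjusted p = 0.00202). Gapdh did not pass (0.62, adjusted p = 0.114). For oxidative phosphorylation 0 of 31 genes were called by limma (0 adjusted over the list alone), and 1 had an unadjusted p under 0.05. The median was 0.27, and −0.09 with quantile scaling (camera adjusted p = 0.0808). That p was 0.0388 without spleen 2, 0.0177 without spleen 4, 0.0474 without heart 2 and 0.0466 with a trend and robust prior. Cox6a1 was at 0.32 (adjusted p = 0.33). NRF2 targets and genes of iron and haem handling had 8 of 19 called higher and 2 lower (10 and 2 adjusted over the list alone). The median was 1.09 (camera adjusted p = 0.00124, adjusted p = 0.106 with an estimated correlation). Slc7a11, the cystine transporter gene, was at least 17.5-fold higher (adjusted p = 0.0143) and Srxn1 rose by 4.14 ± 0.44 (adjusted p = 0.00372). The iron-chelator carrier gene Lcn2, also a neutrophil marker, changed by −5.02 ± 0.47 (adjusted p = 0.0025). The ferritin gene Ftl1 did not pass (0.48, adjusted p = 0.153). In fits without heart 1, heart 2 or heart 4, 3, 4 and 4 glycolysis genes and 4 NRF2 genes each time were called higher; without spleen 4, 10 NRF2 genes were called higher and 3 lower. The calls of Egln3 (adjusted p 0.0978 to 0.109) and Slc7a11 (0.0618 to 0.0687) ended.

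**Figure D2:**
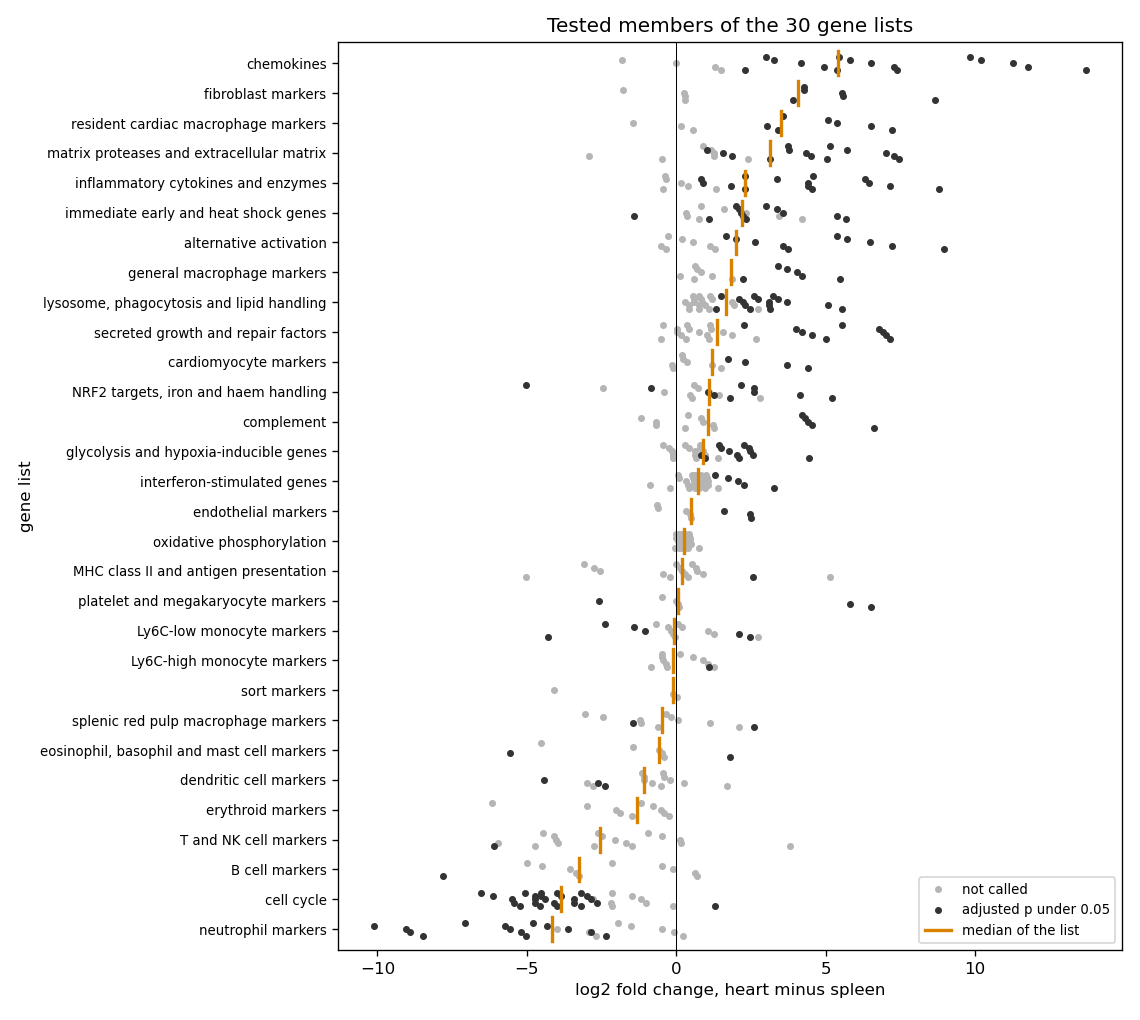
Log2 fold change, heart minus spleen, of each tested member of the 30 gene lists, with called genes (adjusted p under 0.05) in black, others in grey and the list median in orange, and genes below background in a tissue at their fitted value. The medians run from 5.41 for chemokines to −4.15 for neutrophil markers.

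Lists of general and resident cardiac macrophage markers were called higher, while those of red pulp macrophages and of the 2 monocyte subsets did not pass; the lists were not tested against each other. General macrophage markers had 6 of 13 called higher (8 adjusted over the list alone). The median was 1.85 (camera adjusted p = 2.32e-05, adjusted p = 0.232 with an estimated correlation). Among those called were the endotoxin co-receptor gene Cd14 (5.48 ± 0.43, adjusted p = 0.00161) and the complement receptor gene C5ar1 (4.19 ± 0.29, adjusted p = 0.00101). Lyz2, near the top of the signal range where differences can be compressed, did not pass (0.14, adjusted p = 0.816). Markers of resident cardiac macrophages had 7 of 10 called higher (7 adjusted over the list alone), with a median of 3.50 (camera adjusted p = 2.7e-05, adjusted p = 0.124 with an estimated correlation). They were led by Stab1, Pf4 and Ccl24 (5.38 ± 0.43, adjusted p = 0.00171), which are also in the alternative activation or chemokine lists. Of the 10 resident markers, 7 are also in another list, so this rise is not separate from those lists. F13a1 did not pass (0.56, adjusted p = 0.548). Of the Ly6C-high monocyte markers 1 of 12 was called, Ms4a4c (1.11 ± 0.28, adjusted p = 0.045), and none was called adjusted over the list alone, where 2 were higher and 1 lower at an unadjusted p under 0.05. The median was −0.09 and the mean 0.18 (camera adjusted p = 0.832). Plac8 did not pass (0.11, adjusted p = 0.755). Ly6C-low monocyte markers had 2 of 16 called higher and 4 lower (4 and 4 adjusted over the list alone; median −0.07, camera adjusted p = 0.472), with Pglyrp1 at −4.29 ± 0.62 (adjusted p = 0.0102), Spn at −2.37 ± 0.24 (adjusted p = 0.00334), Fabp4 at 2.46 ± 0.52 (adjusted p = 0.028) and Cebpb not called (1.25, adjusted p = 0.0621; 0.0496 without spleen 1 and 0.0344 without spleen 4). Without heart 1, heart 2 or heart 4, 4 general and 4 resident macrophage markers were called each time, and 7, 4 and 9 general ones without spleen 1, 2 or 4. Of the Ly6C-high markers, 2 were called higher and 3 lower without spleen 1, none without spleen 2 or any heart sample, and 3 higher without spleen 4. For Ly6C-low markers the numbers higher and lower were 3 and 3, 1 and 2, and 4 and 3 without spleen 1, 2 or 4, and 1 and 1 without each heart sample. The call of Ms4a4c ended without each heart sample (adjusted p 0.143 to 0.155; 0.0919 without spleen 2), as did those of Pglyrp1 (0.0524 to 0.0558) and Fabp4 (0.083 to 0.0984; 0.0602 without spleen 1 and 0.0715 without spleen 2).

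Red pulp macrophage markers had 1 of 12 called higher, the haem oxygenase gene Hmox1 (2.61 ± 0.24, adjusted p = 0.00259), and 1 lower, Hpgd (−1.44 ± 0.36, adjusted p = 0.0439), with the same counts adjusted over the list alone, a median of −0.48 and a camera adjusted p of 0.4. Fry gave the opposite direction (adjusted p = 0.84). Without spleen 4, 2 were called higher and 4 lower, and without spleen 1 or any heart sample 1 higher and 0 lower. Axl did not pass (1.12, adjusted p = 0.181). Dendritic cell markers had 3 of 15 called lower (5 adjusted over the list alone), with a median of −1.07 (camera adjusted p = 0.00124, adjusted p = 0.256 with an estimated correlation, fry adjusted p = 0.0547). These were Kit (−4.44 ± 1.12, adjusted p = 0.0442, above background on 1 of 3 heart arrays; −3.45 with the floor), Bcl11a (−2.61 ± 0.39, adjusted p = 0.0108) and Irf4 (−2.38 ± 0.46, adjusted p = 0.022). Siglech did not pass (0.28, adjusted p = 0.405). Genes of MHC class II and antigen presentation had 1 of 17 called (1 adjusted over the list alone), the costimulatory gene Cd86 (2.58 ± 0.36, adjusted p = 0.00868). Their median was 0.20 (−0.02 with quantile scaling), the mean −0.15 and the camera adjusted p 0.832, and Ctss, near the top of the signal range, did not pass (0.88, adjusted p = 0.0695; 0.0198 without spleen 4). Without spleen 1, 2 genes of this list were called higher and 4 lower, and without spleen 4, 4 higher and 1 lower; 0 were called without heart 1 or heart 2. Dendritic cell markers had 1 called higher and 2 lower without spleen 1, and 4 lower without spleen 2. No dendritic cell marker was called lower by limma without heart 1 or heart 2, and 1 was without heart 4. Leaving out a heart sample ended the calls of Hpgd (adjusted p 0.121 to 0.154; 0.0525 without spleen 1, 0.0944 with median scaling and 0.0648 with the mean of all tested probes), Kit (0.0721 to 0.133; 0.0959 without spleen 1, 0.113 without spleen 2, 0.0687 with the date block and 0.0514 with quantile scaling) and Irf4 (0.0807 to 0.0949). Those of Bcl11a (0.059 and 0.0584) and Cd86 (0.0511 and 0.0512) ended without heart 1 or heart 2.

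Interferon-stimulated genes had 5 of 32 called higher (5 adjusted over the list alone). The median was 0.74 (camera adjusted p = 0.000529, adjusted p = 0.566 with an estimated correlation, fry adjusted p = 0.146). Among those called were the chemokine gene Cxcl10 (3.27 ± 0.21, adjusted p = 0.00084), Rsad2 (2.27 ± 0.37, adjusted p = 0.0146) and Isg15 (2.07 ± 0.29, adjusted p = 0.00899). Oas1a did not pass (1.06, adjusted p = 0.201; 0.0357 without spleen 4). This list rested on which spleen samples were used, since 24 of its genes were called higher without spleen 4, and within slide 2, which holds spleen 4 and heart 1, its median was −0.13. Without heart 1, heart 2 or heart 4, 1 gene of the list was called each time, and the calls of Rsad2 (adjusted p 0.0685 to 0.0708) and Isg15 (0.0505 to 0.0543) ended. Complement genes had 5 of 14 called higher (5 adjusted over the list alone). The median was 1.06 (camera adjusted p = 0.00559, adjusted p = 0.232 with an estimated correlation). They included the receptor gene C3ar1 (6.61 ± 0.31, adjusted p = 0.000314) and C1qa (4.53 ± 0.79, adjusted p = 0.0168) and C1qb (4.41 ± 0.59, adjusted p = 0.00789), which encode chains of the first component of the classical pathway. C3 did not pass (−0.69, adjusted p = 0.28; 0.0152 without spleen 1). Of the complement genes, 3 were called higher each time a heart sample was left out, 9 higher and 1 lower without spleen 4, and 5 higher and 1 lower without spleen 1. The call of the list ended without a filter on dim probes (camera adjusted p = 0.0857), and the call of C1qa ended without each heart sample (adjusted p 0.0695 to 0.0768). In heart 4 minus spleen 4 the median of complement genes was 0.05.

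Neutrophil markers were lower in heart, with 14 of 22 called lower (18 adjusted over the list alone). The median was −4.15 (camera adjusted p = 7.6e-14, adjusted p = 0.18 with an estimated correlation). The sort had selected cells low for the neutrophil antigen Ly6G in both tissues. Beside Ltf, the granule genes Camp and Ngp changed by −8.46 ± 0.86 (adjusted p = 0.0034) and −10.12 ± 0.83 (adjusted p = 0.00176, Ngp above background on 1 of 3 heart arrays; −9.83 with the floor). Chil1 was at least 127-fold lower (adjusted p = 0.00176), and the receptor gene Csf3r did not pass (−0.06, adjusted p = 0.864, and 0.06 with median scaling). Genes of granulocyte precursors were among the largest falls, with Mpo, the myeloperoxidase gene, at −5.73 ± 1.28 (adjusted p = 0.0316), Ctsg at −5.55 ± 1.19 (adjusted p = 0.0283) and Ms4a3 at least 180-fold lower (adjusted p = 0.007). Itgb2l and Ceacam10 were at least 104.3-fold (adjusted p = 0.00296) and at least 56.0-fold lower (adjusted p = 0.00519), and Mgst2 changed by −5.62 ± 0.71 (adjusted p = 0.00662). The receptor genes Mrgpra2a and Mrgpra2b, whose sequences are close, changed by −6.32 ± 0.85 (adjusted p = 0.00804) and −6.04 ± 0.85 (adjusted p = 0.00943; 0.0526 without heart 4). Without heart 1, heart 2 or heart 4, 9 neutrophil markers were called lower each time. The calls of Mpo (adjusted p 0.0937 to 0.117) and Ctsg (0.0922 to 0.107) ended, as they did without spleen 1 (0.0699 and 0.0632) or spleen 2 (0.0636 and 0.0571).

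Cell cycle genes were lower in heart as a list, with 24 of 33 called lower and 1 higher (31 and 1 adjusted over the list alone). The gene called higher was Tyms (1.31), named after its value was seen. The median was −3.85 (camera adjusted p = 1.83e-15, adjusted p = 0.256 with an estimated correlation). The mitotic genes Nusap1 and Kif11 were at least 40.7-fold (adjusted p = 0.0208) and at least 30.8-fold lower (adjusted p = 0.0144), the ribonucleotide reductase gene Rrm2 changed by −5.49 ± 0.83 (adjusted p = 0.0116) and the kinesin gene Kif22 by −5.60 ± 0.95 (adjusted p = 0.016). Pcna, the sliding clamp of DNA replication, did not pass (−0.12, adjusted p = 0.815, and 0.00 with median scaling). The calls of single genes depended on each heart sample, while their fitted changes moved little. Without heart 1, heart 2 and heart 4, the change was −5.3, −5.7 and −5.5 for Rrm2 and −5.3, −5.6 and −5.9 for Kif22. Without heart 1 or heart 2 limma called 0 cell cycle genes lower and without heart 4 it called 1. The adjusted p was 0.0545 to 0.0706 for Kif11, 0.0593 to 0.0878 for Nusap1, 0.0512 to 0.0599 for Rrm2 and 0.0631 to 0.074 for Kif22. Of the list, 15 genes were called lower without spleen 1, 22 without spleen 2 and 29 without spleen 4. The list itself had a median of −3.81 (camera adjusted p = 3.13e-10) without spleen 1 and −2.53 within slide 2, which holds a single pair. Relative to each gene's mean over the 6 samples, its median was 2.02, 3.60 and 0.20 in spleen 1, 2 and 4, and that of neutrophil markers was 2.72, 2.81 and 0.42. The log2 level of Mpo was 4.26, 5.73 and 0.46 in these samples.

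B cell, T and NK cell and erythroid markers were lower in heart as lists, and these differences lay mainly in spleen 1. B cell markers had 1 of 11 called lower (1 adjusted over the list alone), with a median of −3.24 (camera adjusted p = 0.00691, adjusted p = 0.537 with an estimated correlation). T and NK cell markers had 1 of 18 called lower (1 adjusted over the list alone). Their median was −2.54, or −2.34 with bounds (camera adjusted p = 0.000452, adjusted p = 0.444 with an estimated correlation). Of the erythroid markers 0 of 10 were called by limma (0 adjusted over the list alone, 1 lower at an unadjusted p under 0.05), with a median of −1.32 (camera adjusted p = 0.0213, adjusted p = 0.566 with an estimated correlation). Fry called none of the 3 (adjusted p 0.305, 0.183 and 0.405). Without spleen 1, the medians were −1.33 (camera adjusted p = 0.155), −1.11 (0.000635) and −0.27 (0.338). The calls of the B cell and erythroid lists also ended among probes above background on all 6 arrays (0.122 and 0.0539), and that of the erythroid list without heart 4 (0.0843). Without spleen 1, 7 T and NK cell markers were called lower and 1 higher, and 8 were called lower without spleen 4 and 0 without each heart sample. B cell markers had 2 called higher and 2 lower without spleen 1, 0 without spleen 2, heart 1 or heart 2, and 2 lower without spleen 4. Of the erythroid markers 2 were called lower without spleen 4. Named members were the immunoglobulin joining chain gene Jchain (−7.81 ± 1.75, adjusted p = 0.0322, above background on 1 of 3 heart arrays; −6.50 with the floor), the granzyme gene Gzma (−6.11 ± 1.23, adjusted p = 0.0236) and, outside these lists, the IgM receptor gene Fcmr, at least 68.9-fold lower (adjusted p = 0.0344). Cd79b (−3.37, adjusted p = 0.0942; 0.00822 without spleen 1), Cd4 (0.16, adjusted p = 0.697, and −0.06 with quantile scaling) and Hba-a2 (−0.42, adjusted p = 0.812; 0.61 without spleen 1) did not pass. The calls of Gzma (adjusted p 0.0888 to 0.0937) and Fcmr (0.0999 to 0.124; 0.062 without spleen 2 and 0.0501 with the date block) ended without each heart sample, and that of Jchain without heart 1 or heart 2 (0.115 and 0.117), spleen 1 (0.0688) or spleen 2 (0.0549).

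Of 15 endothelial markers, 8 passed the filter on dim probes and were tested. Endothelial markers had 3 of 8 called higher (3 adjusted over the list alone; median 0.49, camera adjusted p = 0.189, fry adjusted p = 0.0422), Cdh5 (2.50 ± 0.54, adjusted p = 0.0289, above background on 1 of 3 spleen arrays; 2.13 with the floor), Cldn5 (1.59 ± 0.36, adjusted p = 0.0323, on 2 of 3; 1.499) and Fabp4. Kdr did not pass (0.50, adjusted p = 0.16), but was called with the mean of all its tested probes (1.83, adjusted p = 0.00371). Platelet and megakaryocyte markers had 2 of 7 called higher, Pf4 and Ppbp (5.82 ± 1.02, adjusted p = 0.0169), and 1 lower, Itgb3 (−2.59 ± 0.40, adjusted p = 0.0123), whose other tested probe was called in the opposite direction. The same counts held adjusted over the list alone, the median was 0.07 and the camera adjusted p was 0.832. Clec1b did not pass (−0.47, adjusted p = 0.393). Eosinophil, basophil and mast cell markers had 1 of 7 called higher, Mcpt4 (1.80 ± 0.38, adjusted p = 0.0275, above background on 1 of 3 spleen arrays; 1.06 with the floor), and 1 lower, Prg2, at least 10.3-fold lower (adjusted p = 0.01). Adjusted over the list alone these were 1 and 2, the median was −0.59 and the camera adjusted p was 0.0476 (adjusted p = 0.232 with an estimated correlation), a call that ended without spleen 1 (0.114), spleen 2 (0.0714), heart 1 (0.0557) or heart 4 (0.066), with quantile scaling (0.0849), normexp correction (0.0515) or the deposited value table (0.0896), and among probes above background on all 6 arrays (0.09). Ear1 was not called (−0.42, adjusted p = 0.567). Without each heart sample, the calls of Cdh5 (adjusted p 0.0895 to 0.108), Cldn5 (0.0907 to 0.123), Ppbp (0.0695 to 0.0758) and Mcpt4 (0.0837 to 0.112) ended, and those of Cdh5 (0.0777), Cldn5 (0.0821) and Mcpt4 (0.0718) also without spleen 2. No endothelial marker was called without spleen 2 or any heart sample. Of the eosinophil, basophil and mast cell markers, 1 was called higher and 3 lower without spleen 4, and 0 were called without heart 1 or heart 4. The calls of Itgb3 (0.0536 and 0.0587) and Prg2 (0.0531 and 0.0553) ended without heart 1 or heart 4.

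Among further top genes, the leucine-rich membrane protein gene Flrt3 was at least 175-fold higher in heart (adjusted p = 3.61e-05) and the transcription factor gene Maff rose by 6.44 ± 1.22 (adjusted p = 0.0204), a call that ended without each heart sample (0.08 to 0.0848) and without spleen 2 (0.0507). Of the sort markers, Ptprc (CD45) changed by −0.12 ± 0.16 (adjusted p = 0.673, and 0.01 with median scaling) and Itgam (CD11b) by 0.03 ± 0.22 (adjusted p = 0.938, and −0.31 with quantile scaling). Thy1 changed by −4.09 ± 1.64 (adjusted p = 0.145; 0.0341 without spleen 4), with a level of 3.63 in spleen 1, −1.20 in spleen 2, −3.40 in spleen 4 and a mean of −4.41 ± 0.15 (SD, n = 3) in heart. Klrb1c had 2 probes, well above background on at most 2 spleen arrays, the probe of Itga2 was not well above background on any array, and Ly6g had no probe. The 3 tested sort markers had a median of −0.12 and a mean of −1.39 (camera adjusted p = 0.352), and 0 were called by limma (0 adjusted over the list alone, 1 lower at an unadjusted p under 0.05).

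Calls of named genes also changed under other alternatives. Within the earlier date those of C1qa, C1qb, Cdh5, Cldn5, Egr2, Fcmr, Fosb, Gzma, Il6, Irf4, Maff, Mcpt4, Mertk, Ms4a4c, Myl2, Ppbp and Ptgs2 ended (adjusted p 0.0534 to 0.129). Without a filter on dim probes those of Cdh5, Cldn5, Ctsg, Egln3, Fabp4, Fcmr, Hpgd, Jchain, Kit, Mcpt4, Mertk, Mpo, Ms4a4c and Myl2 ended (0.0511 to 0.0906). The replicate block ended those of Cldn5, Fabp4, Fcmr, Kit and Ms4a4c (0.0517 to 0.0938), and the mean of all tested probes those of Itgb3 (−0.36, 0.381), Hpgd and Ms4a4c (0.125). Normexp correction ended that of Fcmr (0.0669), median scaling that of Ms4a4c (0.0722), a random block for slide that of Ms4a4c (0.0516) and array weights that of Jchain (0.0589). Array weights estimated per tissue, chosen after seeing the data, ended those of Cldn5, Fabp4, Jchain and Kit (0.0507 to 0.14). Of the genes not called, array weights called Axl, Ccl6, Cd79b, Cebpb, Ctss, Metrnl, Mydgf, Tgfbi and Thy1 (0.0102 to 0.0439), and weights per tissue Ccl6, Cd79b, Metrnl and Tgfbi (0.0303 to 0.0453). A trend and robust prior called Cebpb, Ctss and Tgfbi (0.0417 to 0.0488), the mean of all tested probes Metrnl (0.0428), and Ccl6 was called with the date block (0.0459) and within the earlier date (0.0361).

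Within slide 2, the only slide with both tissues, and between heart 4 and spleen 4, the only pair of the later date, the medians of neutrophil markers and cell cycle genes were nearer to 0 than over all samples. With slide as a fixed block the contrast rests on the slide 2 pair. The list tests of that fit compare genes and do not measure spread between pairs of samples. Its medians equalled those of the pair, except for alternative activation (2.57) and NRF2 targets (1.15). In the pair they were 5.37 for chemokines, 2.48 for inflammatory genes, 0.998 for repair factors, 2.07 for matrix genes, 2.74 for alternative activation, 0.94 for lysosome genes and 0.97 for glycolysis. They were 1.02 for NRF2 targets, 1.83 for immediate early genes, 1.17 for general and 2.64 for resident macrophage markers, 4.30 for fibroblast and 1.87 for cardiomyocyte markers, and 0.31 for complement. For lists lower in heart they were −2.83 for neutrophil markers, −2.53 for cell cycle genes, −1.23 for dendritic cell, −0.49 for B cell, −0.22 for T and NK cell and −1.02 for eosinophil, basophil and mast cell markers, and 0.65 for erythroid markers. The call of the B cell (camera adjusted p = 0.652), T and NK cell (0.549), eosinophil (0.124), interferon (0.862) and erythroid lists (0.652) ended with that block, and Ly6C-low monocyte markers were called lower with it (−0.66, adjusted p = 0.00939). In the pair of the later date, the medians were 5.89 for chemokines, 2.64 for inflammatory genes, 1.25 for repair factors, 1.72 for matrix genes, 2.87 for alternative activation, 0.95 for lysosome genes, 0.88 for glycolysis, 1.29 for NRF2 targets and 2.12 for immediate early genes. General and resident macrophage markers were at 1.11 and 3.44 there, fibroblast and cardiomyocyte markers at 3.38 and 0.99, complement at 0.05 and interferon-stimulated genes at −0.02. Neutrophil markers were at −2.30, cell cycle genes at −1.96, and dendritic cell, B cell, T and NK cell, erythroid and eosinophil, basophil and mast cell markers at −0.875, −0.65, −0.71, −0.23 and −1.15. Of the 82 called genes that the naming rule picks, 21 were also called with slide as a fixed block (Ccl7, Cxcl3, Cxcl1, Ccl2, Ccl8, Flrt3, Timp1, Thbs1, Spp1, Areg, Stab1, C3ar1, Cd14, Ier3, Egln3, Pdpn, Mgp, Ltf, Ngp, Chil1 and Ceacam10). None of the 82 changed direction with it, which was fixed in advance. In every called gene the values of the tissues did not overlap, so a single pair could not reverse it.

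**Figure D3:**
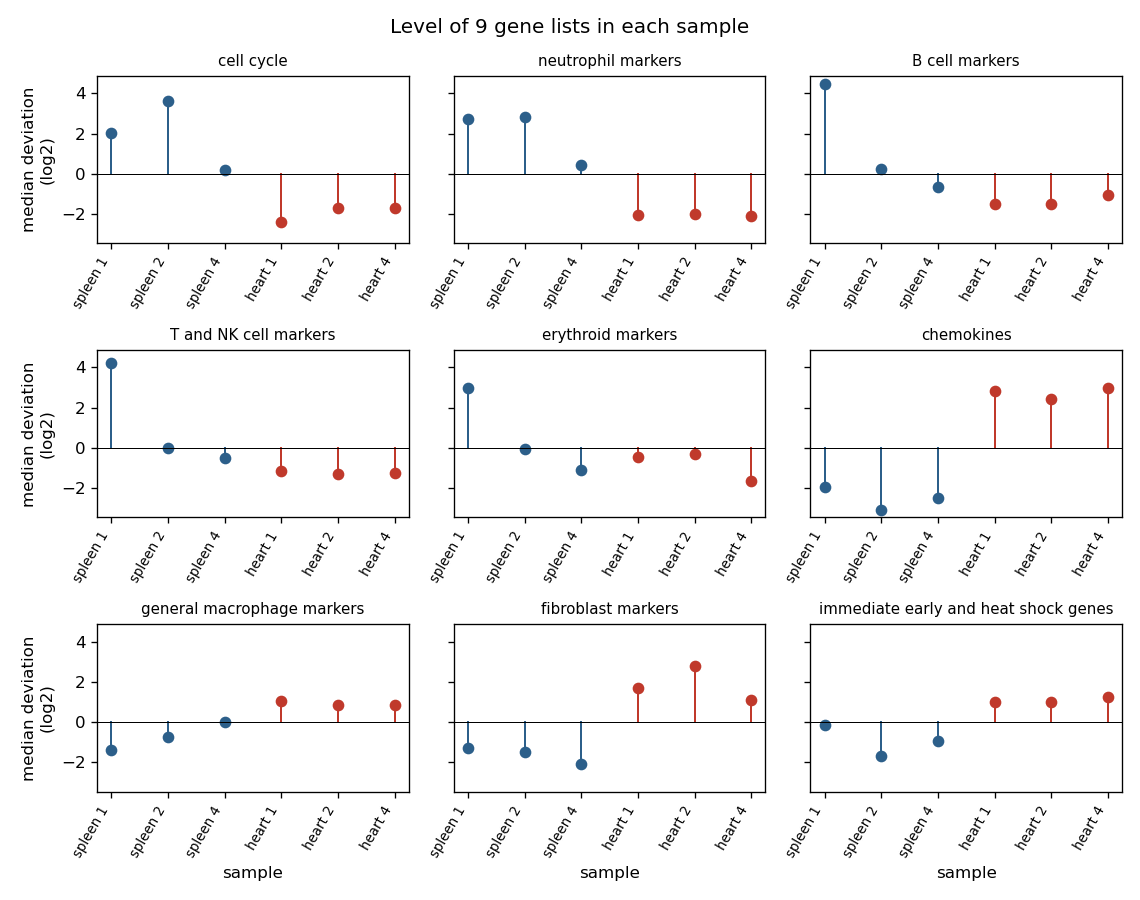
Median deviation, in log2 units, of the genes of 9 lists from each gene's mean over the 6 samples, with a point per sample. B cell markers lie at 4.48 in spleen 1 against 0.23 in spleen 2 and −0.64 in spleen 4, while neutrophil markers lie between −2.07 and −2.00 in the 3 heart samples.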

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

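Slide as a random block and the fits with array weights per tissue or a separate variance per tissue were chosen after seeing the data; the other alternatives were planned. Of the 82 called genes that the naming rule picks, 48 were tested among probes above background on all 6 arrays. None of the 82 changed direction under any alternative that tested it. Since the values of the tissues did not overlap in any of the 82, leaving out samples or resting on the slide 2 pair could not reverse them. The number that kept their call was 80 to 82 under the scalings, normexp correction and the deposited value table, 82 with a trend and robust prior, 81 with array weights, 68 without a filter on dim probes, 65 within the earlier date, 47, 49 and 48 without heart 1, 2 and 4, 21 with slide as a fixed block and 5 with a separate variance per tissue. Of the 22 lists called, 17 to 22 kept their call and direction under the alternatives other than an estimated correlation, which called 0 of 30 (7 at an unadjusted p under 0.05, lowest adjusted p 0.064); fry called 18, 17 of them among the 22.

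Without a filter on dim probes, 28298 genes were tested and 1449 called (928 higher, 521 lower; 1729 probes, against 3263), and correlations within tissues exceeded those between tissues by 0.026, against 0.064. The adjustment then covers more genes; beyond that, the cause was not tested. With slide as a fixed block, 85 genes (72 higher, 13 lower), 85 of them with at least 2-fold change, and 90 probes were called; only slide 2 holds both tissues, so this fit rests on 1 pair. The median of interferon-stimulated genes was then −0.128 (adjusted p = 0.862) and that of erythroid markers 0.648 (adjusted p = 0.652), the reverse of their main direction; the cause was not tested. Within the earlier date, with 4 samples, 2113 probes were called. A separate variance per tissue without moderation called 48 genes (41 higher, 7 lower), 45 with at least 2-fold change, and 63 probes; its few degrees of freedom come from its construction. Stricter thresholds call fewer genes by construction. An adjusted p under 0.01 left 508 genes (368 higher, 140 lower), 508 with at least 2-fold change, and a test against a log2 change of 1 left 323 (243 higher, 80 lower), 323 with at least 2-fold change. Leaving out 1 sample gave 444 to 4090 genes, 321 to 2491 higher and 123 to 1599 lower, 444 to 2962 with at least 2-fold change, and 558 to 5146 probes. The lowest counts came without a heart sample, when more of the pooled variance comes from the more variable spleen samples.

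The replicate block called 1587 genes (919 higher, 668 lower) and 2002 probes. The labels do not state whether the numbers pair the samples. Deviations from the tissue means correlated at −0.068, 0.059 and 0.0074 between samples with the same number, and not every sample correlated best with its own number. With 3 samples per tissue, these correlations cannot decide whether samples with the same number came from the same animal. Signal over background limits the range. The lowest level well above background lay between −5.74 and −4.68 on the log2 scale and the brightest probe between 7.80 and 8.12. Differences of the brightest genes can therefore be compressed (Lyz2, Plac8, Ctss and Chil3 lie there).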

Other observations

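The tests of explanations in this part were chosen after the results were seen. The 3 spleen samples differed from each other in more than the lymphoid and erythroid markers. Relative to each gene's mean over the 6 samples, interferon-stimulated genes had a median of −1.04 in spleen 1, −0.63 in spleen 2 and 0.47 in spleen 4, against 0.33 to 0.43 in the hearts. General macrophage markers were at −1.38, −0.75 and 0.00 in spleen 1, 2 and 4, and at 0.85 to 1.07 in the hearts. Complement genes were at −0.96, −0.67 and 0.12, against 0.44 to 0.63. Cell cycle genes were at 2.02, 3.60 and 0.20, against −2.40 to −1.71. Spleen 4 lay nearest to the mean of the hearts for these 4 lists and for 16 of all 30, and farthest from it for 7, among them alternative activation (−1.80, against −1.07 in spleen 1 and −1.27 in spleen 2), fibroblast markers (−2.10, against −1.29 and −1.47), inflammatory genes (−1.18, against −0.83 and −1.06) and dendritic cell markers (0.76, against 0.56 and −0.13). Spleen 4 is also the spleen sample on the slide it shares with a heart sample and the only spleen sample of the later date, and these cannot be told apart from a difference between animals.

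Genes of granulocyte precursors and of mature neutrophils were set side by side. Of 9 granulocyte precursor genes, written down after the neutrophil result was seen, 8 were called lower in heart, and Elane was not (−1.50, adjusted p = 0.248). Of the transcription factor genes of early granulocyte development, Gfi1 changed by −7.00 (adjusted p = 0.0162, well above background on 1 of 3 heart arrays; −5.90 with the dim arrays at the floor) and Myb was at least 55.8-fold lower (adjusted p = 0.0138). Of 8 genes of mature neutrophils, 2 were called lower (Retnlg −5.21, adjusted p = 0.0239, and Padi4 −1.52, adjusted p = 0.0341) and 1 higher (Trem1 0.90, adjusted p = 0.0203), and the median was −1. Cxcr2 (−3.98, adjusted p = 0.0815) and Mmp9 (−2.93, adjusted p = 0.11) were lower in heart without passing. Mmp8 (−0.49, adjusted p = 0.294), Csf3r (−0.06, adjusted p = 0.864) and Il1r2 (0.50, adjusted p = 0.374) did not pass either. The median thus does not describe each of these genes. The difference between the 2 sets was not tested.

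Slide as the whole cause of the lower neutrophil markers in heart would leave no shift within a slide. The list median was −2.83 with slide as a fixed block. That fit rests on 1 pair, heart 1 and spleen 4, so it cannot measure spread between pairs. The median was −4.15 over all samples, so slide as part of the shift stays open. The markers called lower went from 14 to 6 in that fit, in which all calls went from 2521 to 85. Mature neutrophils alone in the spleen samples would have left granulocyte precursor genes in place, but 8 of the 9 were called lower, among them the 4 outside the neutrophil list that had not been named before (Fcnb, Cebpe, Gfi1 and Myb). Granulocyte precursors in those samples stay open: the median of the 9 genes was −5.55, but the set was written down after the falls were seen and 3 of its genes had already been named for them. Of these genes, Mpo, Ctsg and Prtn3 were at 4.26, 4.31 and 4.21 in spleen 1, 5.73, 5.64 and 5.95 in spleen 2, and 0.46, 0.69 and 3.31 in spleen 4, and 3 of the 22 list genes are also in another list. A difference between myeloid cells of the 2 tissues themselves stays open and was not tested.

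B cell, T and NK cell and erythroid markers were high in spleen 1, although the sort selected cells low for B220, Thy-1.2 and natural killer antigens. A general gain of dim probes in that sample would have raised random genes of the same level alike. The pooled median of the 39 markers was 4.45 above the other spleen samples and exceeded all of 10000 random sets matched on level. These lists were pooled after they were seen to be high there, and small shifts also ranked high in this comparison. Neutrophil markers (0.04) lay above 99.33% of matched sets and cell cycle genes (0.30) above 99.9%. In the same comparison, general macrophage markers were at −1.03 and Ly6C-high monocyte markers at −1.04, and 0% of matched sets were lower. B cells, T and NK cells and erythroid cells in that sample stay open. Whether they account for these lower values was not tested, and the pattern of their own markers cannot decide. In that pattern, 89.7% of the markers (35 of 39) lay at least 1 log2 unit above both other spleen samples, against 5.26% of 16340 genes, with Hba-a2 at 7.59 in spleen 1, 5.13 in spleen 2 and 3.85 in spleen 4, and Cd79b at 5.69, 1.44 and 1.57. Of the B cell, T and NK cell and erythroid lists, only that of T and NK cells shares a gene (1) with another list. No biological explanation was tested.

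Slide as the whole cause of the higher chemokines in heart would leave no shift within a slide. The list median was 5.37 with slide as a fixed block, against 5.41 over all samples. That fit rests on the same pair; the chemokines called higher went from 16 to 8 in it, while the median stayed. Stress during tissue handling stays open, since 11 immediate early and heat shock genes were called higher in heart and the same cells could express both in the tissue. Fibroblasts in the heart samples also stay open, since 6 of their markers were called higher and fibroblasts can secrete chemokines, although the sort selected cells high for CD45, which fibroblasts lack. Both cannot be told apart from expression by the myeloid cells, because each follows the tissue. Of the 10 splits of the 6 samples into 3 and 3, only 1, the split by tissue, called as many genes as 2521. The highest other split called 0 by limma (440 at an unadjusted p under 0.05 in the highest other split). Every other split puts both tissues in each group, so the tissue difference widens its spread and its count does not measure chance. Also, 10 splits are too few for a share under 0.05.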
